A study of Mus musculus with 9 samples.

How the data were processed

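Colon RNA of 9 libraries, 3 each of Normal, Model and Atorvastatin, was sequenced from 1.3 µg of total RNA, per the labels' protocols. bcl2fastq 2.0, HISAT2, StringTie and DESeq2 are named in the submitters' processing notes, without their roles or order, together with the builds rn6 and mm39. The authors deposited whole-number estimated counts per gene, unscaled, for 21720 genes with coordinates. The build is not written in the table; the coordinates are not those of GRCm38, and mm39 is the mouse build that the notes name. Low values pile up at multiples of 4 (1997 values of 4 against 346 values of 1), so 1 read pair was taken as about 4 estimated counts. Of the symbols, 21053 matched the reference annotation, which was used only for names and gene types. A gene at 0 counts in a group was given a bound at 3 read pairs, or 12 estimated counts, over the 3 libraries of that group. Folds whose lower group held few read pairs carry a 95% interval for counting error alone.

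Groups, comparisons, tests, the 37 gene lists and the rule for naming genes were chosen before the data were examined. With R 4.3.3 and edgeR 4.0.16, genes were filtered by filterByExpr, which left 16160 (3481 had 0 counts in every library), libraries were scaled by TMM, and a quasi-likelihood model with group as its only term was fitted to all 9 libraries. Each pair of groups was tested on both sides, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The SE beside a log2 fold change is its absolute value divided by the square root of the F statistic of that test. CPM values were computed here from the TMM-scaled library sizes. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01, and adjusted over 111 tests for the 37 lists and over 15 tests for the lists added later; camera with a correlation estimated per list and fry were run beside it. List members that the table lacks were not analysed here: Pla2g2a, Mx1, Mx2, Trac, Trbc1, Trbc2, Igha, Ighm, Igkc, Prac1 and Ahsp. The genes named are the 5 largest rises and falls past the threshold with a mean of at least 1 CPM and no overlap between groups, the 2 members with the smallest p of each list (at least for the 6 lists with the smallest p), and Tnf, Il1b, Il6, Il22, Lcn2, Muc2, Tjp1, Ocln, Ahr, Cyp1a1 and Ido1. Some genes that the rule picks are not reported here. Genes outside the rule are marked as chosen after their values were seen.

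Tested on simulated data with 200 changed genes in each of 10 simulations of 16160 genes, the test for Model against Normal recovered 0.75% of 1.5-fold, 17.3% of 2-fold and 67.3% of 4-fold changes, with 4.88% false among the calls. For Atorvastatin against Model 5.07% of the calls were false. The recovery rates may be too high, since libraries simulated in a similar way gave more calls than the real ones. Shared libraries were allowed for by 100 simulations in which a group did not differ. Alternatives chosen beforehand were DESeq2 1.42.0 size factors, upper-quartile scaling, TMM without abundant genes, DESeq2, limma-voom, other filters, only the 2 groups compared, an added fold threshold, the replicate number as a block, and leaving out each library. Alternatives chosen after seeing the data were counts divided by 4, library size alone, covariates for acinar genes and for colon region, and leaving out Model 2 and 3 together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.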

Results

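Messenger RNA was measured by RNA-seq in the colon of female C57BL/6J mice in 3 groups of 3 libraries each. The Normal group received the vehicle, 0.5% sodium carboxymethyl cellulose, by gavage over 7 days. The Model group received 5% dextran sulfate sodium (DSS), a polymer that injures the colonic epithelium and is widely used to model ulcerative colitis, over 7 days. The Atorvastatin group received 10 mg/kg atorvastatin, a statin that inhibits cholesterol synthesis, in 0.2 mL once a day over 5 days, from day 3 to day 7. The labels do not say outright whether the Atorvastatin group also received DSS. They also do not say in so many words that each library came from a separate mouse, so the p-values measure the spread between these libraries, which may be technical. Total estimated counts, rounded to 6 digits, were 72584300, 80694200 and 76874700 in Normal 1 to 3, 87755700, 91737500 and 74945900 in Model 1 to 3 and 78778500, 84017600 and 77741600 in Atorvastatin 1 to 3. Of 21720 genes, 16160 were tested. No pair of libraries of a group agreed within counting noise. The median absolute log2 ratio between libraries of a group was 0.17 to 0.31, against at most 0.05 from counting alone.

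On the first principal component, which held 27.0% of the variance, Normal libraries lay at -82.0 to -42.4, Model libraries at 33.5 to 59.2 and Atorvastatin libraries at 7.49 to 27.6. Pancreatic acinar genes, which encode digestive enzymes and include near-identical trypsinogen copies of uncertain counts, held 7.91% of the counts in Model 2 and 3.37% in Model 3. The same genes held 0.0137% in Model 1, 0.166%, 0.164% and 0.0143% in Normal 1 to 3, and 0.318%, 0.138% and 0.00475% in Atorvastatin 1 to 3. Genes of small intestinal enterocytes were abundant in Model 3, with 3214 estimated counts of sucrase-isomaltase (Sis), 3445 of lactase (Lct) and 4358 of Apoa1. These 3 genes were chosen after their values were seen. In the other 8 libraries Sis reached at most 218, Lct at most 34 and Apoa1 at most 57 estimated counts. 

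Model was compared with Normal to ask what DSS changed in the colon. Genes that rose in Model included 14 of 19 neutrophil and monocyte genes, 9 of 15 macrophage genes, 10 of 26 cytokines and chemokines and 7 of 16 antigen-presentation genes. Among the stromal lists, 12 of 20 matrix genes, 9 of 15 fibroblast genes and 5 of 17 endothelial genes rose. Among the genes that fell were 3 of 14 stem cell genes and the antimicrobial ribonuclease gene Ang4. These lists passed camera with a preset correlation, and 0 of the 17 lists that did so held with an estimated correlation (adjusted p = 0.444 to 0.509 for those named here). Other splits of the Normal and Model libraries also called 6 to 16 lists with the preset correlation. In all, 883 of 16160 genes changed, 706 higher and 177 lower, and 625 of them by at least 1 on the log2 scale. Nos2, the inducible nitric oxide synthase, rose from 23.4 ± 9.58 to 346 ± 63.1 CPM (mean ± SD, n = 3 libraries each; log2 fold change 3.89 ± 0.33 (SE), adjusted p = 0.00257; chromosome 11, 78811613 to 78851080, mm39). Coordinates are those of the authors' table, and mm39 is the mouse build named in the submitters' processing notes.

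Among the largest rises, Prss22, a serine protease of epithelia, had 0 counts in the Normal libraries and 4.71 ± 2.72 CPM in Model, at least 89.5-fold higher (adjusted p = 0.00306; chromosome 17, 24212508 to 24217074). The bound takes 3 read pairs, about 12 estimated counts over the 3 libraries, as the limit that a count of 0 allows. Cldn2, a pore-forming claudin, rose 901-fold (counting interval 308 to 4373), with 45.1 ± 62.7 CPM in Model and 0.0554 ± 0.0375 CPM in Normal (adjusted p = 0.0299; chromosome X, 138701577 to 138712135). S100a9, a subunit of calprotectin, rose 329-fold (counting interval 112 to 1600.3; adjusted p = 0.0124; chromosome 3, 90599939 to 90603028). Tarm1, a myeloid receptor, rose 149-fold (counting interval 26.4 to 5932; adjusted p = 0.00875; chromosome 7, 3535016 to 3551140). Fetub rose 86.2-fold (counting interval 23.5 to 718; adjusted p = 0.0319; chromosome 16, 22737084 to 22758528). Single libraries weighed on Cldn2 and Fetub: in Model 1 to 3, Cldn2 had 18.3, 117 and 0.204 CPM and Fetub 0.248, 4.21 and 5.03 CPM, the latter mostly in the libraries with abundant acinar RNA. The adjusted p of Cldn2 was 0.0975 without Normal 1, 0.0903 without Normal 2, 0.133 without Normal 3 and 0.0550 without Model 1. That of Fetub was 0.0902 without Normal 1, 0.0876 without Normal 2, 0.127 without Normal 3, 0.0647 without Model 2 and 0.0509 without Atorvastatin 2. Normal held at most 3 read pairs of each of these 4 genes, and the intervals cover counting error only. Among the largest falls were those of Ang4 (13.6 ± 9.78 CPM in Model and 1589 ± 1263 CPM in Normal; log2 fold change -6.87 ± 1.17, adjusted p = 0.0145; chromosome 14, 52001335 to 52011047), Pla2g4c (log2 fold change -5.96 ± 1.18, adjusted p = 0.0252; chromosome 7, 13058580 to 13094597), Smpx (log2 fold change -4.24 ± 1.03, adjusted p = 0.0468; chromosome X, 156481906 to 156535585) and Frmd3 (log2 fold change -3.89 ± 0.88, adjusted p = 0.0394; chromosome 4, 73931679 to 74120451). Ang4 has close paralogs in the angiogenin family, so its counts are uncertain. By the naming rule, the libraries of the 2 groups did not overlap for any of these genes.

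Genes of innate immune cells and their signals rose together. Of 19 tested neutrophil and monocyte genes, 14 rose and 5 did not pass, with 18 higher when adjusted over the list alone. Neutrophil and monocyte genes had a median log2 fold change of 3.38 (camera adjusted p = 2.66e-15, adjusted p = 0.444 with an estimated correlation). Csf3r, the receptor for granulocyte colony-stimulating factor, rose from 3.18 ± 1.5 to 22.1 ± 4.97 CPM (log2 fold change 2.79 ± 0.39, adjusted p = 0.00780). The lectin receptor Clec4e rose as well (log2 fold change 4.79 ± 0.74, adjusted p = 0.0108). Of 26 cytokines and chemokines, 10 rose and 16 did not pass, with 20 higher adjusted over the list alone. Inflammatory cytokines and chemokines had a median log2 fold change of 2.58 (camera adjusted p = 3.57e-13, adjusted p = 0.444 with an estimated correlation). The median was 2.39 with Il17a and Csf3, both at 0 counts in Normal, set to their bounds. Cxcl5, a neutrophil attractant, rose from 0.0908 ± 0.0299 to 5.74 ± 2.32 CPM (log2 fold change 5.95 ± 0.70, adjusted p = 0.00431). The monocyte attractant Ccl2 rose as well (log2 fold change 2.82 ± 0.34, adjusted p = 0.00445). Il1b rose from 5.65 ± 4.66 to 45.0 ± 12.4 CPM (log2 fold change 2.99 ± 0.58, adjusted p = 0.0234) and Tnf from 3.19 ± 2.86 to 18.1 ± 3.39 CPM (log2 fold change 2.5 ± 0.57, adjusted p = 0.0400). Il6 was 23.3-fold (counting interval 8.79 to 87.1) higher, on 4 read pairs in Normal, without passing (adjusted p = 0.125). Il22, a cytokine acting on epithelium, was 31.0-fold (counting interval 8.24 to 262) higher, on 2 read pairs in Normal, also without passing (adjusted p = 0.0876).

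Of 15 macrophage genes, 9 rose, with 11 higher adjusted over the list alone (median log2 fold change 1.35, camera adjusted p = 6.91e-09, adjusted p = 0.444 with an estimated correlation), among them the growth factor receptor Csf1r (109 ± 4.78 CPM in Model and 42.1 ± 7.98 CPM in Normal; log2 fold change 1.38 ± 0.16, adjusted p = 0.00431) and Cd68 (log2 fold change 1.70 ± 0.22, adjusted p = 0.00574). Of 16 genes of MHC class II and antigen presentation, 7 rose, with 15 higher adjusted over the list alone. MHC class II and antigen presentation had a median log2 fold change of 1.22 (camera adjusted p = 1.96e-08, adjusted p = 0.509 with an estimated correlation). The invariant chain gene Cd74 rose from 428 ± 196 to 1983 ± 114 CPM (log2 fold change 2.21 ± 0.39, adjusted p = 0.0168), and H2-DMa, a peptide-loading chaperone, rose as well (log2 fold change 2.05 ± 0.32, adjusted p = 0.0110). Genes of the H2 family resemble each other in sequence, so their counts are uncertain. Among 15 T and NK cell genes 1 rose, Ctla4 (log2 fold change 1.65 ± 0.37, adjusted p = 0.0389), with 5 higher adjusted over the list alone and all 15 positive. T and NK cell genes had a median log2 fold change of 1.04 (camera adjusted p = 5.20e-04, adjusted p = 0.643 with an estimated correlation). Without Normal 3, the list means (log2 CPM) differed by 0.56 instead of 1.04. Cd4 did not pass (log2 fold change 1.22 ± 0.35, adjusted p = 0.0792). Interferon-stimulated genes did not pass as a list (median -0.50, adjusted p = 0.718), although 2 of 18 rose, Gbp2 (log2 fold change 2.0 ± 0.41, adjusted p = 0.0273) and Irf1 (log2 fold change 0.76 ± 0.17, adjusted p = 0.0353). None of 14 B and plasma cell genes and none of 12 mast cell and eosinophil genes passed in edgeR's test, over all genes or adjusted over the list alone. Their medians were -0.74 (adjusted p = 0.515) and 0.39 (adjusted p = 0.505).

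Matrix, fibroblast and endothelial genes rose as lists. Of 20 genes of matrix and tissue remodelling, 12 rose, with 18 higher adjusted over the list alone. Matrix and tissue remodelling had a median log2 fold change of 1.51 (camera adjusted p = 2.90e-10, adjusted p = 0.444 with an estimated correlation). Mmp3, stromelysin, rose from 1.16 ± 0.341 to 26 ± 14.2 CPM (log2 fold change 4.49 ± 0.79, adjusted p = 0.0158) and the collagen gene Col1a2 rose as well (log2 fold change 1.21 ± 0.22, adjusted p = 0.0169). Of 15 fibroblast genes, 9 rose, with 11 higher adjusted over the list alone. Fibroblast genes had a median log2 fold change of 0.96 (camera adjusted p = 7.51e-08, adjusted p = 0.444 with an estimated correlation). The fibroblast genes that rose included Grem1, a BMP antagonist (191 ± 84.8 CPM in Model and 33.7 ± 6.96 CPM in Normal; log2 fold change 2.5 ± 0.41, adjusted p = 0.0136), and Pdpn (log2 fold change 1.85 ± 0.29, adjusted p = 0.0117). Of 17 endothelial genes, 5 rose, with 14 higher adjusted over the list alone (median log2 fold change 0.91, camera adjusted p = 7.51e-08, adjusted p = 0.444 with an estimated correlation), such as the leukocyte adhesion molecule Icam1 (log2 fold change 1.48 ± 0.26, adjusted p = 0.0164) and Eng (log2 fold change 1.47 ± 0.25, adjusted p = 0.0147). Gfap, a glial filament gene, rose (log2 fold change 1.91 ± 0.39, adjusted p = 0.0274) as 1 of 15 enteric neuron and glia genes, a list that did not pass (median 0.33, adjusted p = 0.220). Enteric neuron and glia genes passed as higher without Model 3 (adjusted p = 0.00690).

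Among the epithelial lists, members of the antimicrobial and stress-response list went both ways, with 5 of 18 higher and 1 lower. Adjusted over the list alone, 8 were higher and 1 lower. Colon RNA does not show which cells carried these changes. Epithelial antimicrobial and stress response had a median log2 fold change of 0.92 (camera adjusted p = 0.00221, adjusted p = 0.444 with an estimated correlation). Nos2 rose and Ang4 fell, as above, and Lcn2, an iron-sequestering antimicrobial protein, rose from 2.42 ± 0.699 to 25.3 ± 13.2 CPM (log2 fold change 3.38 ± 0.58, adjusted p = 0.0147). Of 14 stem cell genes 3 fell, with 1 higher and 5 lower adjusted over the list alone. Intestinal stem cell genes had a median log2 fold change of -0.50 (camera adjusted p = 5.20e-04, adjusted p = 0.469 with an estimated correlation). Without Model 1, the list means (log2 CPM) differed by -0.43 instead of -0.73. Axin2, a Wnt target, fell from 23.8 ± 3.56 to 4.53 ± 1.81 CPM (log2 fold change -2.40 ± 0.31, adjusted p = 0.00574; chromosome 11, 108811175 to 108841609), and Ephb3 fell as well (log2 fold change -1.48 ± 0.25, adjusted p = 0.0144). Of 20 cell cycle genes 1 fell, the mitotic kinase gene Plk1 (log2 fold change -0.67 ± 0.14, adjusted p = 0.0299), also the 1 gene lower adjusted over the list alone, and 19 of 20 were negative. Cell cycle genes had a median log2 fold change of -0.50 (camera adjusted p = 8.95e-06, adjusted p = 0.617 with an estimated correlation). None of 16 goblet cell and mucus genes passed in edgeR's test, over all genes or adjusted over the list alone, although the list fell. Goblet cell and mucus genes had a median log2 fold change of -0.52 (camera adjusted p = 0.0156, adjusted p = 0.643 with an estimated correlation). The adjusted p of this list was 0.102 without Model 1. The values were -2.47 ± 0.64 for Clca1 (adjusted p = 0.0590) and -0.58 ± 0.33 for the mucin Muc2 (adjusted p = 0.364). Cldn2 was the 1 of 19 tight junction and adhesion genes that rose, in a list that did not pass (median 0.13, adjusted p = 0.257), with Tjp1 at 0.40 ± 0.15, adjusted p = 0.182. Ocln was at -0.23 ± 0.23, adjusted p = 0.625.

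For the pathways tied to atorvastatin and to the aim named in the series title, tryptophan metabolism, some genes rose and few lists passed. Ido1, the first enzyme of the kynurenine pathway, rose from 20.3 ± 17.5 to 449 ± 361 CPM (log2 fold change 4.47 ± 0.85, adjusted p = 0.0214; chromosome 8, 25074152 to 25087025). The tryptophanyl-tRNA synthetase gene Wars rose as well (log2 fold change 1.52 ± 0.30, adjusted p = 0.0238). These were the 2 of 22 tryptophan genes that rose, and the list did not pass (median 0.23, adjusted p = 0.411). Of 13 aryl hydrocarbon receptor targets 1 fell, Nqo1 (log2 fold change -0.92 ± 0.22, adjusted p = 0.0430), with 1 higher and 2 lower adjusted over the list alone (median 0.18, adjusted p = 0.446), while Ahr was at 0.11 ± 0.14, adjusted p = 0.709. Cyp1a1 was at 1.82 ± 1.35, adjusted p = 0.492. None of 24 genes of cholesterol synthesis and uptake passed in edgeR's test, over all genes or adjusted over the list alone (median -0.01, adjusted p = 0.530). Cholesterol efflux and LXR targets rose as a list, with 2 of 13 higher, also adjusted over the list alone (median log2 fold change 0.51, camera adjusted p = 0.00493, adjusted p = 0.444 with an estimated correlation), namely the cholesterol exporter Abca1 (log2 fold change 1.15 ± 0.25, adjusted p = 0.0331) and the ileal bile acid-binding protein gene Fabp6 (log2 fold change 3.73 ± 0.77, adjusted p = 0.0291). Fabp6 is also 1 of the 3 small intestinal genes that rose. In Model 1 to 3 it had 28.6, 7.16 and 38.9 CPM, Abcg5 14.3, 0.560 and 22.2 CPM and Abcg8 6.60, 0.706 and 10.4 CPM, each highest in Model 3 with its small intestinal RNA, so such RNA may add to the rise. Abcg5 and Abcg8, chosen after their values were seen, did not pass, and the list also passed without Model 3. Of 19 fatty acid oxidation and PPAR targets 3 rose, among them Angptl4 (log2 fold change 2.38 ± 0.49, adjusted p = 0.0281) and Acadl (log2 fold change 0.90 ± 0.17, adjusted p = 0.0234), in a list that did not pass (median 0.01, adjusted p = 0.975). Xenobiotic metabolism fell as a list with 1 of 21 genes lower, and 3 adjusted over the list alone. Xenobiotic metabolism had a median log2 fold change of -0.41 (camera adjusted p = 0.0106, adjusted p = 0.617 with an estimated correlation). The adjusted p of this list was 0.0801 without Normal 2 and 0.0703 without Model 2. That gene was Cyp2c55, a colonic cytochrome P450, which fell from 417 ± 127 to 78.6 ± 37.5 CPM (log2 fold change -2.41 ± 0.42, adjusted p = 0.0151).

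The 13 mitochondrially encoded genes fell as a list, with 0 passing over all genes in edgeR's test and 4 lower adjusted over the list alone. Mitochondrially encoded genes had a median log2 fold change of -0.47 (camera adjusted p = 8.95e-06, adjusted p = 0.547 with an estimated correlation). Smooth muscle genes fell as a list with 0 of 15 passing, also adjusted over the list alone. Smooth muscle genes had a median log2 fold change of -0.45 (camera adjusted p = 0.0478, adjusted p = 0.794 with an estimated correlation). The adjusted p of this list was 0.194 without Normal 1, 0.0699 without Normal 3, 0.702 without Model 3 and 0.0536 without Atorvastatin 2. Erythrocyte genes rose as a list with 0 of 7 passing and 4 higher adjusted over the list alone. Erythrocyte genes had a median log2 fold change of 1.76 (camera adjusted p = 0.0338, adjusted p = 0.617 with an estimated correlation). The adjusted p of this list was 0.0877 without Model 1 and 0.0703 without Model 2. Globin copies are near-identical and their counts uncertain. The other lists did not pass: absorptive colonocyte genes at a median of -0.18 (adjusted p = 0.515), enteroendocrine and tuft cell genes at -0.09 (adjusted p = 0.418), the unfolded protein response at -0.19 (adjusted p = 0.382), adipocyte genes at -0.31 (adjusted p = 0.275), skeletal muscle genes at -0.19 (adjusted p = 0.400), proximal colon region genes at -0.75 (adjusted p = 0.0954), distal colon region genes at 0.11 (adjusted p = 0.519), nuclear oxidative phosphorylation genes at -0.11 (adjusted p = 0.138) and immediate early genes at 0.26 (adjusted p = 0.137). Pancreatic acinar genes stood at 5.27 (adjusted p = 0.0505) and small intestinal genes at 1.96 (adjusted p = 0.0588), with their RNA mostly in Model 2 and 3 and in Model 3, as described. The distal region list had a positive median while camera placed it lower, and the stem cell list had a mean of -0.09 against its median of -0.50. Some of these passed without 1 library. Pancreatic acinar genes passed as higher without Normal 1 (adjusted p = 0.0215), without Normal 2 (adjusted p = 0.0205), without Model 1 (adjusted p = 2.00e-07), without Atorvastatin 1 (adjusted p = 0.0332), without Atorvastatin 2 (adjusted p = 0.0325) and without Atorvastatin 3 (adjusted p = 0.0150). Small intestinal genes passed as higher without Model 1 (adjusted p = 0.00174), without Model 2 (adjusted p = 0.00463), without Atorvastatin 1 (adjusted p = 0.0234), without Atorvastatin 2 (adjusted p = 0.0278) and without Atorvastatin 3 (adjusted p = 0.0464). Adipocyte genes passed as lower without Normal 2 (adjusted p = 0.0480) and without Model 2 (adjusted p = 0.0235). Nuclear oxidative phosphorylation genes passed as lower without Normal 3 (adjusted p = 0.0360) and without Model 3 (adjusted p = 0.0470). Adjusted over the list alone, 3 of 17 immediate early genes were higher. Of 17 unfolded protein response genes 1 fell, Ern2 (-0.62 ± 0.14, adjusted p = 0.0414), and of 12 adipocyte genes 1, Pck1 (-1.38 ± 0.23, adjusted p = 0.0142). Among the small intestinal genes 3 of 11 rose, and 5 adjusted over the list alone, including Fabp6 and Ace (log2 fold change 1.38 ± 0.29, adjusted p = 0.0320). Among the proximal colon genes 3 of 10 fell, including Cyp2c55 and the metalloprotease gene Mep1a (log2 fold change -1.28 ± 0.20, adjusted p = 0.0116).

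These calls come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 called 1966 genes, 1347 higher and 619 lower, and scaling by library size alone called 502 higher and 244 lower. Leaving out 1 library moved the count of 883 to 320 without Normal 1, 499 without Normal 2, 164 without Normal 3, 364 without Model 1, 573 without Model 2, 563 without Atorvastatin 2 and 579 without Atorvastatin 3. With Model 2 and 3 both left out, an alternative chosen after seeing the data, 476 genes were called. The Model group is then the single library Model 1, assumed to vary like the other groups, so this count is no replicated check against acinar RNA. Of the 47 genes of the naming rule that passed, 12 passed without any 1 library, namely Prss22, Tarm1, Cxcl5, Ccl2, Csf3r, Clec4e, Csf1r, Cd68, Nos2, H2-DMa, Axin2 and Mep1a. The other 35 lost the call at least once, 26 of them without Normal 1, 13 without Normal 2, 34 without Normal 3, 22 without Model 1, 14 without Model 2, 4 without Model 3, 5 without Atorvastatin 1, 7 without Atorvastatin 2 and 8 without Atorvastatin 3, with adjusted p of at most 0.162. Of 37 lists 17 passed, 11 higher and 6 lower, 13 of them without any 1 library; 0 held with an estimated correlation, and 8 passed by fry.

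**Figure D1:**
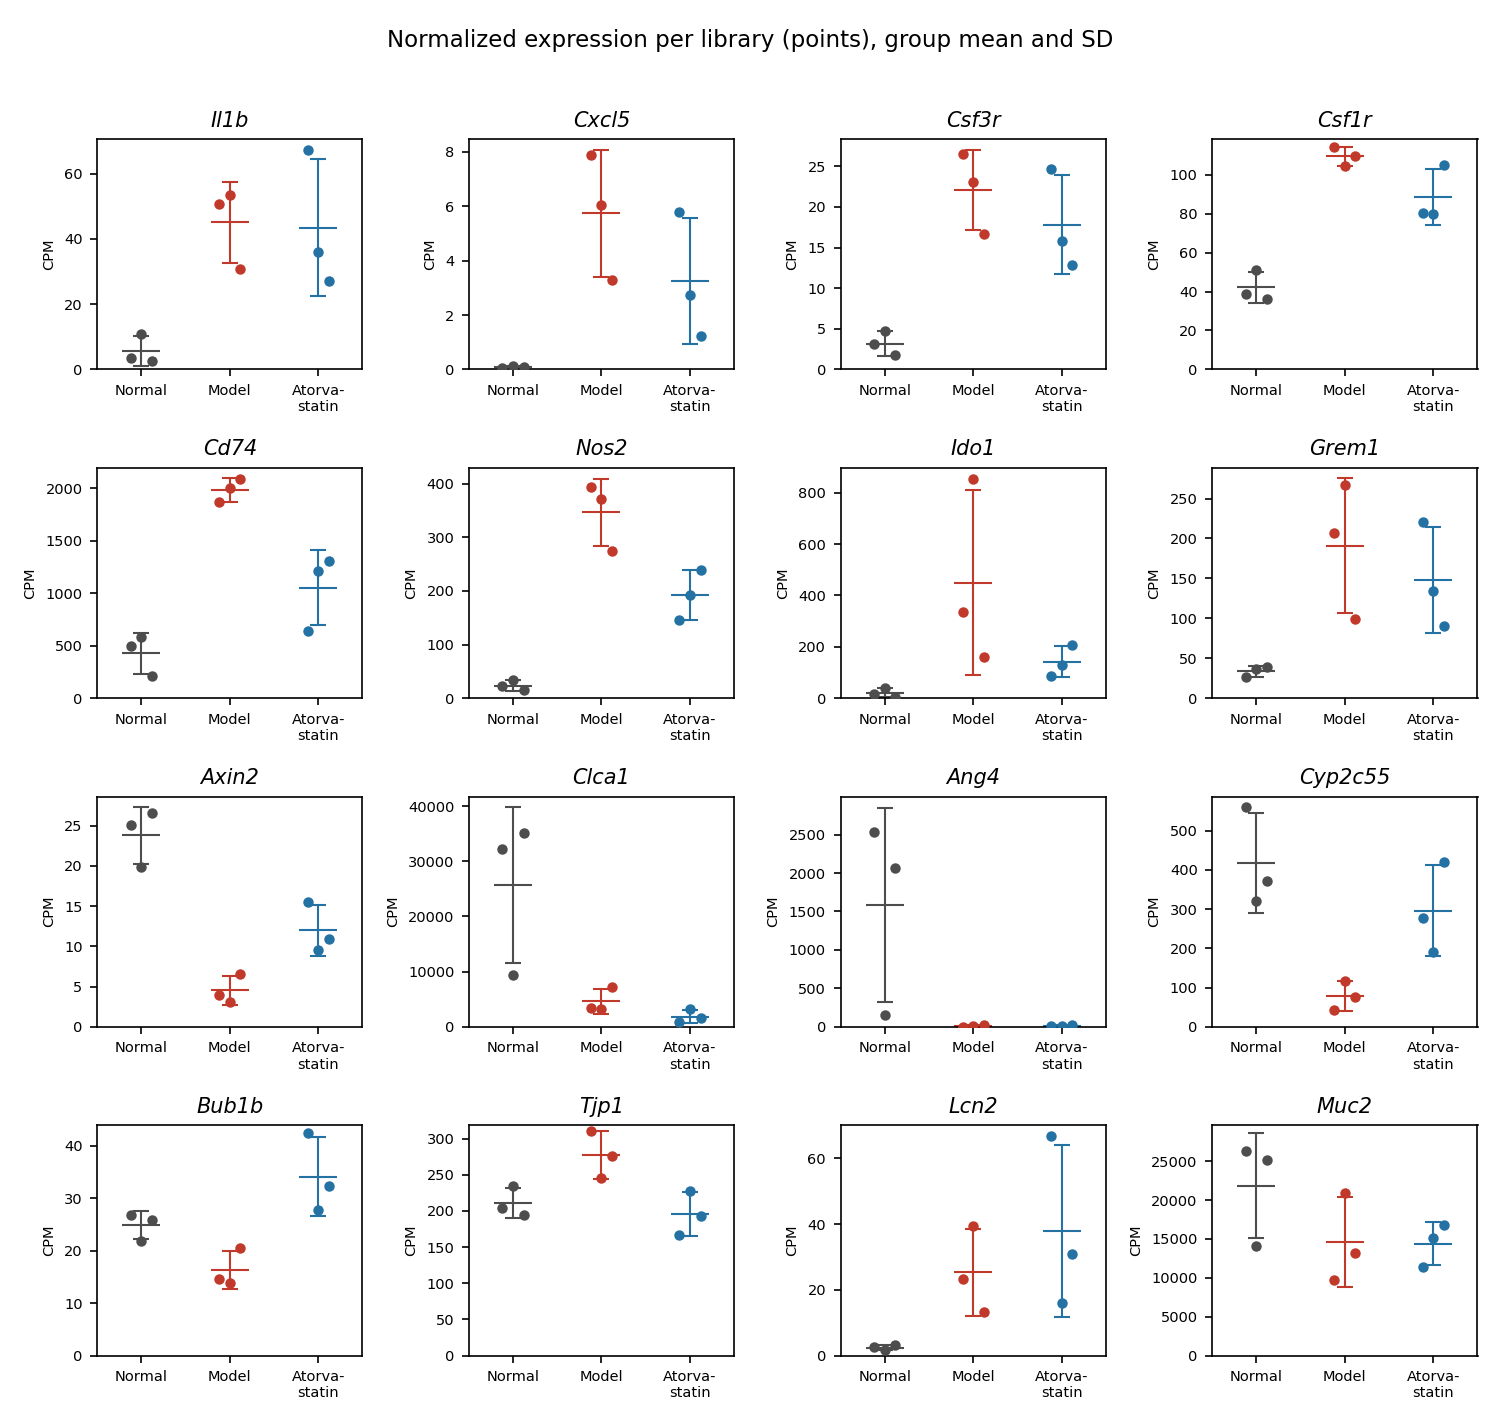
Normalized expression (CPM, linear axes from 0) of 16 genes in the 9 libraries; points are libraries, horizontal bars group means and whiskers the SD (n = 3). Nos2 went from 23.4 ± 9.58 to 346 ± 63.1 CPM between Normal and Model and Axin2 from 23.8 ± 3.56 to 4.53 ± 1.81 CPM, while Muc2 did not pass in any comparison.

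Atorvastatin was compared with Model to ask how the drug group differed from the DSS group. Cell cycle and stem cell genes were higher in Atorvastatin than in Model as lists, and antigen-presentation, endothelial, smooth muscle and tryptophan-metabolism genes were lower as lists. These list calls use a preset correlation of 0.01, and 0 of the 10 hold with an estimated correlation. Of the 9 other splits of these 6 libraries, 8 also called 10 to 19 lists. No single gene passed. edgeR's quasi-likelihood test called 0 of 16160 genes, with a smallest adjusted p of 0.322. At an unadjusted p under 0.05 there were 1908 genes, 962 higher and 946 lower. DESeq2 called 321 genes and limma-voom 0. In simulated data for this comparison, edgeR recovered 1.79% of genes changed by 1.5-fold, 16.4% of those changed by 2-fold and 69.4% of those changed by 4-fold. These rates may be too high: libraries simulated in a similar way called 1670 genes in Model against Normal on average, against 883 in the real ones. By fry 0 lists passed.

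All 20 cell cycle genes were higher in Atorvastatin, 19 of them past the threshold adjusted over the list alone. Cell cycle genes had a median log2 fold change of 0.93 (camera adjusted p = 2.66e-15, adjusted p = 0.444 with an estimated correlation). The spindle checkpoint gene Bub1b stood at 34.1 ± 7.54 CPM in Atorvastatin and 16.4 ± 3.66 CPM in Model (log2 fold change 1.06 ± 0.21, adjusted p = 0.322), and Aurkb, a mitotic kinase, at 17.4 ± 4.62 CPM in Atorvastatin and 8.10 ± 1.86 CPM in Model (log2 fold change 1.11 ± 0.24, adjusted p = 0.322). The mean log2 CPM of the list was 5.22 ± 0.33 in Atorvastatin and 4.35 ± 0.35 in Model (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Of 14 stem cell genes 11 were positive, 5 of them higher adjusted over the list alone. Intestinal stem cell genes had a median log2 fold change of 0.47 (camera adjusted p = 3.71e-04, adjusted p = 0.468 with an estimated correlation). Without Model 1, the list means (log2 CPM) differed by 0.38 instead of 0.67. Axin2 stood at 12.0 ± 3.17 CPM in Atorvastatin and 4.53 ± 1.81 CPM in Model (log2 fold change 1.41 ± 0.30, adjusted p = 0.322) and Ascl2, a stem cell transcription factor, at 1.93 ± 0.58 (adjusted p = 0.330). All 16 antigen-presentation genes were lower, with 0 past the threshold adjusted over the list alone. MHC class II and antigen presentation had a median log2 fold change of -0.53 (camera adjusted p = 8.37e-06, adjusted p = 0.617 with an estimated correlation). Without Atorvastatin 1, the list means (log2 CPM) differed by -0.40 instead of -0.72. Here H2-Aa stood at 585 ± 173 CPM in Atorvastatin and 1335 ± 282 CPM in Model (log2 fold change -1.19 ± 0.38, adjusted p = 0.331), and Ciita, the master regulator of MHC class II, at -1.07 ± 0.39 (adjusted p = 0.359).

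Endothelial genes were lower in 16 of 17, smooth muscle genes in 15 of 15 and absorptive colonocyte genes in 19 of 22, and in edgeR's test 0 of them passed adjusted over the list alone. Endothelial genes had a median log2 fold change of -0.41 (camera adjusted p = 0.00221, adjusted p = 0.617 with an estimated correlation), and an adjusted p of 0.0717 without Model 2. The lymphatic marker Lyve1 stood at -0.71 ± 0.21, adjusted p = 0.330. The VEGF receptor gene Kdr was at -0.59 ± 0.18, adjusted p = 0.330. Smooth muscle genes had a median log2 fold change of -0.44 (camera adjusted p = 0.00334, adjusted p = 0.657 with an estimated correlation), and an adjusted p of 0.148 without Model 1. Without Model 1 or Atorvastatin 1, the list means (log2 CPM) differed by -0.17 or -0.24 instead of -0.40. Kcnmb1 was at -0.56 ± 0.19, adjusted p = 0.344. Cnn1 was at -0.63 ± 0.25, adjusted p = 0.374. Absorptive colonocyte genes had a median log2 fold change of -0.24 (camera adjusted p = 0.0116, adjusted p = 0.617 with an estimated correlation), and an adjusted p of 0.103 without Atorvastatin 1. Ceacam20 was at -0.78 ± 0.23, adjusted p = 0.327. Pancreatic acinar genes were lower in 13 of 13, with 0 passing adjusted over the list alone, and small intestinal genes in 10 of 11, with 3 lower adjusted over the list alone. Pancreatic acinar genes had a median log2 fold change of -4.92 (camera adjusted p = 0.00696, adjusted p = 0.781 with an estimated correlation), and an adjusted p of 0.215 without Model 2, 0.186 without Model 3 and 0.159 without Atorvastatin 3. Small intestinal genes had a median log2 fold change of -2.20 (camera adjusted p = 0.00599, adjusted p = 0.617 with an estimated correlation), and an adjusted p of 0.338 without Model 3. The acinar RNA lay mostly in Model 2 and 3 and the small intestinal RNA in Model 3. Apoa1 was at -8.10 ± 2.19, adjusted p = 0.323. Ace was at -1.10 ± 0.29, adjusted p = 0.323.

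Tryptophan metabolism genes were lower in 19 of 22, with 0 past the threshold adjusted over the list alone (median log2 fold change -0.49, camera adjusted p = 0.0191, adjusted p = 0.544 with an estimated correlation), and the list adjusted p was 0.189 without Model 3 and 0.0926 without Atorvastatin 1. The exact permutation p of the list mean was 0.1. Ido1 was at 141 ± 60.8 CPM in Atorvastatin and 449 ± 361 CPM in Model (log2 fold change -1.67 ± 0.75, adjusted p = 0.426), and the neutral amino acid transporter gene Slc6a19 at -1.52 ± 0.70, adjusted p = 0.441. Slc6a19 is also expressed in small intestine. Aryl hydrocarbon receptor targets did not pass (median 0.00, adjusted p = 0.975), with 2 of 13 higher adjusted over the list alone. Nqo1 was at 0.83 ± 0.22, adjusted p = 0.323. Ugt1a6a was at 1.28 ± 0.28, adjusted p = 0.323. Ahr was at 0.00 ± 0.14, adjusted p = 0.999. Cyp1a1 was at -3.25 ± 1.44, adjusted p = 0.424. Il22 was at -3.07 ± 1.25, adjusted p = 0.387. The mean of the receptor targets was -0.39, of opposite sign to their median. Ugt1a6a and Ugt1a1 share exons, so their counts are uncertain. Xenobiotic metabolism did not pass (median -0.02, adjusted p = 0.290), with 2 of 21 higher adjusted over the list alone; Cyp2c55 was at 296 ± 115 CPM in Atorvastatin and 78.6 ± 37.5 CPM in Model (log2 fold change 1.91 ± 0.41, adjusted p = 0.322) and Ugt1a1 at 1.48 ± 0.40, adjusted p = 0.323. Xenobiotic metabolism passed as higher without Model 3 (adjusted p = 0.0382).

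Cholesterol synthesis and uptake genes had a median of 0.07 (adjusted p = 0.479), with 0 of 24 past the threshold in edgeR's test adjusted over the list alone, and the list passed without Model 1 (adjusted p = 0.0112). In simulations, a shift of this list by 0.25 was called in 7 of 10 runs and a shift by 0.5 in 10 of 10. The simulated genes vary independently, while the estimated correlation of this list was 0.53, and 0 of 360 unshifted lists were called there against 9 to 19 lists in other splits of the real libraries. The simulated rates may therefore be too high, and the missing call does not exclude such a shift. Cholesterol efflux and LXR targets were lower in 11 of 13, with 1 lower adjusted over the list alone (median log2 fold change -0.25, camera adjusted p = 0.0184, adjusted p = 0.469 with an estimated correlation), at an adjusted p of 0.10 without Model 1 and 0.0666 without Atorvastatin 1. Among them the exporter gene Abcg1 was at 17.3 ± 2.73 CPM in Atorvastatin and 30.7 ± 4.33 CPM in Model (log2 fold change -0.83 ± 0.21, adjusted p = 0.323). Fatty acid oxidation and PPAR targets did not pass (median 0.08, adjusted p = 0.418).

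Inflammatory lists did not pass in this comparison: cytokines and chemokines had a median of -0.06 (adjusted p = 0.408), neutrophil and monocyte genes -0.07 (adjusted p = 0.221), macrophage genes -0.22 (adjusted p = 0.310), interferon-stimulated genes 0.13 (adjusted p = 0.295), T and NK cell genes -0.20 (adjusted p = 0.284), B and plasma cell genes -0.48 (adjusted p = 0.201), mast cell and eosinophil genes -0.50 (adjusted p = 0.176) and the antimicrobial list -0.25 (adjusted p = 0.235). Tnf was at -0.74 ± 0.54, adjusted p = 0.641. Il1b was at -0.05 ± 0.54, adjusted p = 0.984. Il6 was at 0.08 ± 1.21, adjusted p = 0.989. Lcn2 was at 0.58 ± 0.53, adjusted p = 0.724. The barrier lists did not pass either, with goblet cell and mucus genes at -0.42 (adjusted p = 0.0883) and tight junction and adhesion genes at -0.14 (adjusted p = 0.139); Muc2 was at -0.02 ± 0.33, adjusted p = 0.990. Tjp1 was at -0.50 ± 0.15, adjusted p = 0.330. Ocln was at -0.19 ± 0.23, adjusted p = 0.809. Matrix and tissue remodelling genes stood at -0.14 (adjusted p = 0.287), fibroblast genes at -0.18 (adjusted p = 0.188), enteric neuron and glia genes at 0.04 (adjusted p = 0.625) and enteroendocrine and tuft cell genes at -0.25 (adjusted p = 0.235). The unfolded protein response stood at -0.01 (adjusted p = 0.228), mitochondrially encoded genes at -0.10 (adjusted p = 0.314), nuclear oxidative phosphorylation genes at 0.01 (adjusted p = 0.773) and immediate early genes at 0.04 (adjusted p = 0.515). Adipocyte genes stood at 0.09 (adjusted p = 0.505), skeletal muscle genes at -0.62 (adjusted p = 0.329), proximal colon region genes at -0.10 (adjusted p = 0.857), distal colon region genes at -0.59 (adjusted p = 0.154) and erythrocyte genes at -0.79 (adjusted p = 0.405). The proximal colon genes moved apart rather than not at all, with 4 of 10 higher and 4 lower adjusted over the list alone (quartiles -1.68 to 1.56). They include Cyp2c55, which was higher, and Saa1 and the zymogen granule gene Sycn, which were lower. Sycn is also a gene of pancreatic acinar cells. Acinar RNA lay mostly in Model 2 and 3, so the lower Sycn may reflect that RNA. Of 14 B and plasma cell genes 1 was lower adjusted over the list alone, Derl3 (-1.81 ± 0.38, adjusted p = 0.322). Median, mean and test differed in sign for some lists: the means were 0.02 for interferon-stimulated genes, 0.14 for proximal colon genes, -0.03 for nuclear oxidative phosphorylation genes and 0.08 for immediate early genes, and camera placed all 4 lower. Many of these lists passed without 1 library. Inflammatory cytokines and chemokines passed as lower without Atorvastatin 1 (adjusted p = 0.0117). Neutrophil and monocyte genes passed as lower without Model 3 (adjusted p = 0.0271) and without Atorvastatin 1 (adjusted p = 0.00212). Interferon-stimulated genes passed as higher without Atorvastatin 1 (adjusted p = 3.97e-04) and as lower without Atorvastatin 3 (adjusted p = 0.00225). T and NK cell genes passed as lower without Atorvastatin 3 (adjusted p = 0.00417). B and plasma cell genes passed as lower without Model 2 (adjusted p = 0.0156) and without Atorvastatin 3 (adjusted p = 0.0236). Goblet cell and mucus genes passed as lower without Model 1 (adjusted p = 0.00221) and without Atorvastatin 2 (adjusted p = 0.0276). Tight junction and adhesion genes passed as lower without Atorvastatin 2 (adjusted p = 0.0327). Matrix and tissue remodelling passed as lower without Model 3 (adjusted p = 0.00568) and without Atorvastatin 1 (adjusted p = 0.00164). Fibroblast genes passed as lower without Model 3 (adjusted p = 0.00690) and without Atorvastatin 1 (adjusted p = 0.0179). Enteric neuron and glia genes passed as higher without Model 2 (adjusted p = 0.0121). Enteroendocrine and tuft cell genes passed as lower without Atorvastatin 3 (adjusted p = 0.0203). Mitochondrially encoded genes passed as lower without Model 1 (adjusted p = 0.00614) and without Atorvastatin 1 (adjusted p = 0.0242). Immediate early genes passed as lower without Atorvastatin 1 (adjusted p = 0.0244). Distal colon region genes passed as lower without Atorvastatin 2 (adjusted p = 0.0276). A list that misses the threshold is not shown to be equal between the groups.

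Of the 883 genes changed in Model against Normal, 785 (88.9%) had the opposite sign in Atorvastatin against Model. The share was 89.8% of the 706 genes that rose and 85.3% of the 177 that fell. Both comparisons use the Model libraries, which alone raises the share: with Atorvastatin libraries simulated to be like Model it was 65.0% on average over 100 simulations (62.2 to 68.0%), in which 1670 genes were called in Model against Normal on average, more than the 883 observed. The covariance of the fold changes was -0.36, against -0.15 in those simulations, a difference of -0.20, and the correlation across genes, which are not independent replicates, was -0.54 against -0.26. With the 6 Model and Atorvastatin libraries assigned in all 20 ways, 3 assignments gave at least the real share, the real one included. The others were 94.7% with Model 1, Model 2 and Atorvastatin 1 taken as Model and 92.1% with Model 1, Model 2 and Atorvastatin 3. Assignments other than the real one spanned 10.8 to 94.7%. The simulated genes varied independently, so the simulated range may be too narrow. By library size alone, an alternative chosen after seeing the data, the share was 76.0%, with 67.7% of the 502 genes that rose and 93.0% of the 244 that fell. The simulations gave 62.2% (59.0 to 65.6%) for the genes that rose and 71.5% (65.7 to 76.6%) for those that fell. None of the 785 passed by edgeR in Atorvastatin against Model. The share was 88.8% without Normal 1, 89.6% without Normal 2, 90.9% without Normal 3, 87.6% without Model 1, 85.5% without Model 2, 94.5% without Model 3, 92.9% without Atorvastatin 1, 78.7% without Atorvastatin 2 and 85.1% without Atorvastatin 3.

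**Figure D2:**
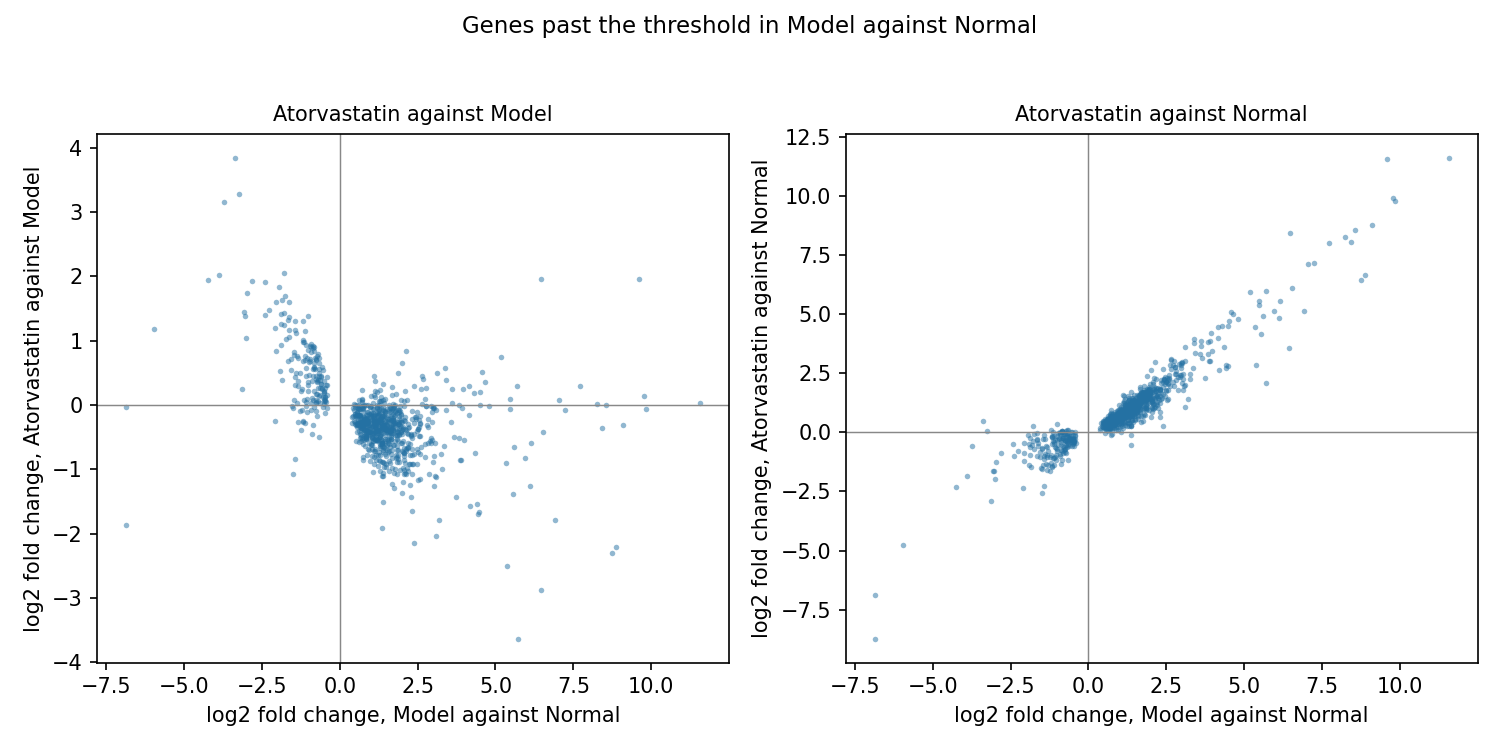
Log2 fold changes of the 883 genes past the threshold in Model against Normal (horizontal axes), against those in Atorvastatin against Model (left) and Atorvastatin against Normal (right); each point is a gene. On the left, 785 genes lie in the quadrants of opposite sign, or 88.9%, against 65.0% in simulations in which Atorvastatin did not differ from Model and up to 94.7% in other assignments of the same libraries.

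Atorvastatin was compared with Normal to ask how far the drug group stood from vehicle. Genes that rose in Atorvastatin included 7 of 19 neutrophil and monocyte genes, 7 of 26 cytokines and chemokines, 3 of 15 macrophage genes, 6 of 20 matrix genes and 3 of 15 fibroblast genes. Goblet cell, smooth muscle and mitochondrially encoded genes were lower as lists, with 1 of 16, 0 of 15 and 0 of 13 genes passing in edgeR's test. All of these lists passed camera with a preset correlation, and 0 of 21 held with an estimated correlation (adjusted p = 0.444 to 0.544 for those named here). Other splits of the Normal and Atorvastatin libraries also called 9 to 18 lists with the preset correlation. In all, 270 of 16160 genes changed, 214 higher and 56 lower, 225 of them by at least 1 on the log2 scale. Of these, 205 also rose and 30 also fell in Model against Normal. Independent lists of these sizes would share 9.35 and 0.613 genes. Simulated unchanged groups with the same controls shared 0.01 and 0.01, but few genes can pass there at all, so this count is no baseline. With Atorvastatin simulated like Model, 883.5 (842 to 932) and 282 (241 to 312) genes were shared. Those simulations called 1670 genes in Model against Normal on average, more than the 883 observed, so their shared counts may be too high. The covariance of the 2 sets of fold changes was 0.52, against 0.15 with no group differing, a difference of 0.37. The correlation across genes was 0.69 against 0.50. With 3 Normal libraries the controls could not be split, so part of the excess of shared genes may come from the shared controls. The simulated covariance holds their part only on average. The simulated genes varied independently, so the real shared libraries could give more or less.

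Prss22 had 4.83 ± 0.925 CPM and was at least 91.8-fold higher than in Normal (adjusted p = 0.00562). Cldn2 rose 3362-fold (counting interval 1150.1 to 16304), with 176 ± 45.3 CPM in Atorvastatin and 0.0554 ± 0.0375 CPM in Normal (adjusted p = 0.0316). S100a9 rose 324-fold (counting interval 110.5 to 1572; adjusted p = 0.0217) and Tarm1 151-fold (counting interval 26.8 to 6005; adjusted p = 0.0153). Cxcl2, a neutrophil attractant, rose from 0.132 ± 0.0702 to 8.19 ± 5.81 CPM (log2 fold change 5.94 ± 0.74, adjusted p = 0.0129; chromosome 5, 91051730 to 91053797). Among the largest falls were those of Ang4 (log2 fold change -6.89 ± 1.17, adjusted p = 0.0255), Clca1, a goblet cell mucus protein (1858 ± 1252 CPM in Atorvastatin and 25610.5 ± 14134 CPM in Normal; log2 fold change -3.78 ± 0.68, adjusted p = 0.0297; chromosome 3, 144709578 to 144738537), the tubulin-binding protein gene Tppp (23.5 ± 4.47 CPM in Atorvastatin and 175 ± 31.6 CPM in Normal; log2 fold change -2.89 ± 0.21, adjusted p = 0.00275; chromosome 13, 74157538 to 74183872) and the clock-controlled transcription factor gene Dbp (7.59 ± 1.88 CPM in Atorvastatin and 45.3 ± 9.70 CPM in Normal; log2 fold change -2.58 ± 0.26, adjusted p = 0.00562; chromosome 7, 45354512 to 45359627).

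Of 19 neutrophil and monocyte genes 7 rose, with 17 higher adjusted over the list alone. Neutrophil and monocyte genes had a median log2 fold change of 3.18 (camera adjusted p = 2.66e-15, adjusted p = 0.444 with an estimated correlation). The neutrophil and monocyte genes that rose included Clec4e (log2 fold change 4.78 ± 0.74, adjusted p = 0.0196) and Csf3r (log2 fold change 2.48 ± 0.39, adjusted p = 0.0210). Of 26 cytokines and chemokines 7 rose, with 18 adjusted over the list alone (median log2 fold change 2.6, camera adjusted p = 6.50e-14, adjusted p = 0.444 with an estimated correlation; 2.49 with Il17a and Csf3 at their bounds), including Cxcl5 (log2 fold change 5.13 ± 0.68, adjusted p = 0.0133) and Il1b (log2 fold change 2.94 ± 0.58, adjusted p = 0.0442). Il6 was 25-fold (counting interval 9.49 to 93.2) higher without passing (adjusted p = 0.186), as was Il22 at 3.91-fold (counting interval 0.809 to 37.2; adjusted p = 0.609). Tnf was at 1.76 ± 0.56, adjusted p = 0.168. Of 15 macrophage genes 3 rose, with 12 adjusted over the list alone. Macrophage genes had a median log2 fold change of 1.12 (camera adjusted p = 2.90e-10, adjusted p = 0.444 with an estimated correlation). The macrophage genes that rose included Cd68 (log2 fold change 1.46 ± 0.22, adjusted p = 0.0177) and Csf1r (log2 fold change 1.07 ± 0.16, adjusted p = 0.0177). Of 20 matrix genes 6 rose, with 15 higher and 1 lower adjusted over the list alone. Matrix and tissue remodelling had a median log2 fold change of 1.43 (camera adjusted p = 7.06e-10, adjusted p = 0.444 with an estimated correlation). The matrix genes that rose included Timp1, an inhibitor of metalloproteinases (log2 fold change 3.60 ± 0.59, adjusted p = 0.0224), and the collagen cross-linking enzyme gene Lox (log2 fold change 3.02 ± 0.50, adjusted p = 0.0233). Of 15 fibroblast genes 3 rose, with 9 adjusted over the list alone. Fibroblast genes had a median log2 fold change of 0.91 (camera adjusted p = 1.01e-07, adjusted p = 0.444 with an estimated correlation). The fibroblast genes that rose included Pdpn (log2 fold change 1.59 ± 0.29, adjusted p = 0.0339) and Pdgfra (log2 fold change 1.24 ± 0.24, adjusted p = 0.0380). In the antimicrobial list 3 of 18 rose and 1 fell, with 4 higher and 1 lower adjusted over the list alone (median log2 fold change 0.71, camera adjusted p = 0.0168, adjusted p = 0.512 with an estimated correlation; adjusted p = 0.0537 without Normal 3), including Nos2 (log2 fold change 3.04 ± 0.32, adjusted p = 0.00659) and Lcn2 (log2 fold change 3.96 ± 0.60, adjusted p = 0.0177).

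Antigen-presentation genes rose as a list with 0 of 16 passing in edgeR's test and 1 higher adjusted over the list alone (median log2 fold change 0.75, camera adjusted p = 7.64e-04, adjusted p = 0.657 with an estimated correlation). Without Normal 3 or Atorvastatin 3, the list means (log2 CPM) differed by 0.34 or 0.42 instead of 0.65. Cd74 was at 1.29 ± 0.38, adjusted p = 0.148. Endothelial genes rose as a list with 0 of 17 passing and 5 higher adjusted over the list alone. Endothelial genes had a median log2 fold change of 0.53 (camera adjusted p = 1.99e-04, adjusted p = 0.547 with an estimated correlation). T and NK cell genes rose as a list with 0 of 15 passing, also adjusted over the list alone (median log2 fold change 0.70, camera adjusted p = 0.00264, adjusted p = 0.70 with an estimated correlation; adjusted p = 0.111 without Normal 3 and 0.0654 without Atorvastatin 3). Goblet cell genes fell as a list with 1 of 16 lower, and 4 adjusted over the list alone (median log2 fold change -0.64, camera adjusted p = 8.95e-06, adjusted p = 0.465 with an estimated correlation). Muc2 was at -0.60 ± 0.34, adjusted p = 0.444. All 13 mitochondrially encoded genes were lower, 0 passing over all genes and 12 adjusted over the list alone (median log2 fold change -0.56, camera adjusted p = 6.81e-09, adjusted p = 0.465 with an estimated correlation), with mt-Atp8 at -0.97 ± 0.24, adjusted p = 0.0895 and mt-Nd4l at -0.56 ± 0.15, adjusted p = 0.107. Each of these genes overlaps a neighbour, so its counts are uncertain. Smooth muscle genes fell as a list with 0 of 15 passing and 8 lower adjusted over the list alone. Smooth muscle genes had a median log2 fold change of -0.90 (camera adjusted p = 3.31e-06, adjusted p = 0.544 with an estimated correlation). Synm was at -1.64 ± 0.37, adjusted p = 0.0636. Proximal colon region genes fell as a list with 0 of 10 passing and 2 lower adjusted over the list alone. Proximal colon region genes had a median log2 fold change of -0.86 (camera adjusted p = 0.00847, adjusted p = 0.444 with an estimated correlation). Without Normal 1, the list means (log2 CPM) differed by -0.38 instead of -0.61.

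Further lists passed on weaker evidence, each lost without at least 1 library. Cell cycle genes were higher, at 0.40 (camera adjusted p = 0.0132, adjusted p = 0.792 with an estimated correlation), with an adjusted p of 0.176 without Normal 2 and 0.333 without Atorvastatin 1. Absorptive colonocyte genes were lower, at -0.40 (camera adjusted p = 0.00264, adjusted p = 0.547 with an estimated correlation), with 0.0501 without Atorvastatin 1. Distal colon region genes were lower, at -0.60 (camera adjusted p = 0.0338, adjusted p = 0.465 with an estimated correlation), with 0.0834 without Normal 2, 0.0517 without Model 3 and 0.0659 without Atorvastatin 1. B and plasma cell genes were lower, at -1.23 (camera adjusted p = 0.0338, adjusted p = 0.781 with an estimated correlation), with 0.288 without Normal 1, 0.0834 without Normal 2 and 0.325 without Atorvastatin 2. Enteroendocrine and tuft cell genes were lower, at -0.37 (camera adjusted p = 0.0306, adjusted p = 0.644 with an estimated correlation), with 0.123 without Normal 3 and 0.395 without Atorvastatin 1, and xenobiotic metabolism was lower, at -0.49 (camera adjusted p = 0.0338, adjusted p = 0.643 with an estimated correlation), with 0.147 without Normal 2, 0.110 without Atorvastatin 1 and 0.123 without Atorvastatin 2. The unfolded protein response was lower, at -0.12 (camera adjusted p = 0.0279, adjusted p = 0.624 with an estimated correlation), with 0.218 without Normal 1, 0.0528 without Atorvastatin 2 and 0.0759 without Atorvastatin 3, and nuclear oxidative phosphorylation genes were lower, at -0.12 (camera adjusted p = 0.0420, adjusted p = 0.681 with an estimated correlation), with 0.169 without Normal 1, 0.101 without Normal 2, 0.0540 without Model 1, 0.0511 without Model 2, 0.0601 without Atorvastatin 2 and 0.107 without Atorvastatin 3.

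The pathways of the series' aim did not pass as lists against Normal. Tryptophan metabolism had a median of -0.37 (adjusted p = 0.366), with Ido1 at 141 ± 60.8 CPM in Atorvastatin and 20.3 ± 17.5 CPM in Normal (log2 fold change 2.80 ± 0.78, adjusted p = 0.124). Aryl hydrocarbon receptor targets had 0.09 (adjusted p = 0.366), with Ahr at 0.11 ± 0.14, adjusted p = 0.779. Cyp1a1 was at -1.43 ± 1.38, adjusted p = 0.696. Cholesterol synthesis and uptake had -0.02 (adjusted p = 0.774) and cholesterol efflux had 0.15 (adjusted p = 0.330), with 3 of 13 higher adjusted over the list alone, Abca1, Nr1h4 and Fabp6. In fatty acid oxidation and PPAR targets, at 0.05 (adjusted p = 0.418), 1 of 19 rose, Angptl4 (log2 fold change 2.68 ± 0.49, adjusted p = 0.0340). Tight junction genes stood at -0.10 (adjusted p = 0.768), with Tjp1 at -0.10 ± 0.15, adjusted p = 0.822. Ocln was at -0.42 ± 0.23, adjusted p = 0.438. Stem cell genes stood at -0.21 (adjusted p = 0.192), interferon-stimulated genes at -0.27 (adjusted p = 0.203), mast cell and eosinophil genes at -0.54 (adjusted p = 0.578), enteric neuron and glia genes at 0.31 (adjusted p = 0.0861), adipocyte genes at -0.19 (adjusted p = 0.446) and skeletal muscle genes at -0.66 (adjusted p = 0.0883). Pancreatic acinar genes stood at 0.34 (adjusted p = 0.773), small intestinal genes at -0.05 (adjusted p = 0.974), erythrocyte genes at 0.84 (adjusted p = 0.0746) and immediate early genes at 0.32 (adjusted p = 0.235). Adjusted over the list alone, 4 of 17 immediate early genes were higher and 2 lower, and 2 of 15 enteric neuron and glia genes higher, Gfap and Nos1. Erythrocyte genes passed as higher without Normal 1 (adjusted p = 0.0319), without Normal 2 (adjusted p = 0.0230), without Model 1 (adjusted p = 0.0443), without Model 3 (adjusted p = 0.0167) and without Atorvastatin 3 (adjusted p = 0.0165). Interferon-stimulated genes passed as lower without Normal 3 (adjusted p = 0.0360) and without Atorvastatin 3 (adjusted p = 0.00112). Enteric neuron and glia genes passed as higher without Model 2 (adjusted p = 0.0481) and without Model 3 (adjusted p = 0.0348). Intestinal stem cell genes passed as lower without Atorvastatin 1 (adjusted p = 0.0140). Camera placed the acinar, tight junction and stem cell lists lower although their means were 0.38, 0.64 and 0.26.

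The count of 270 from edgeR's quasi-likelihood test was 34 without Normal 1, 167 without Normal 2, 17 without Normal 3, 64 without Atorvastatin 1 and 93 without Atorvastatin 3, and DESeq2 called 1056 and limma-voom 141. Of the 24 genes of the naming rule that passed, 4 passed without any 1 library, namely Prss22, Tppp, Dbp and Nos2. The calls lost were 19 without Normal 1, 10 without Normal 2, 20 without Normal 3, 5 without Model 1, 2 without Model 2, 13 without Atorvastatin 1, 3 without Atorvastatin 2 and 10 without Atorvastatin 3, with adjusted p of at most 0.174. Of 37 lists 21 passed, 10 higher and 11 lower, 11 of them without any 1 library; 0 held with an estimated correlation, and 6 passed by fry.

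**Figure D3:**
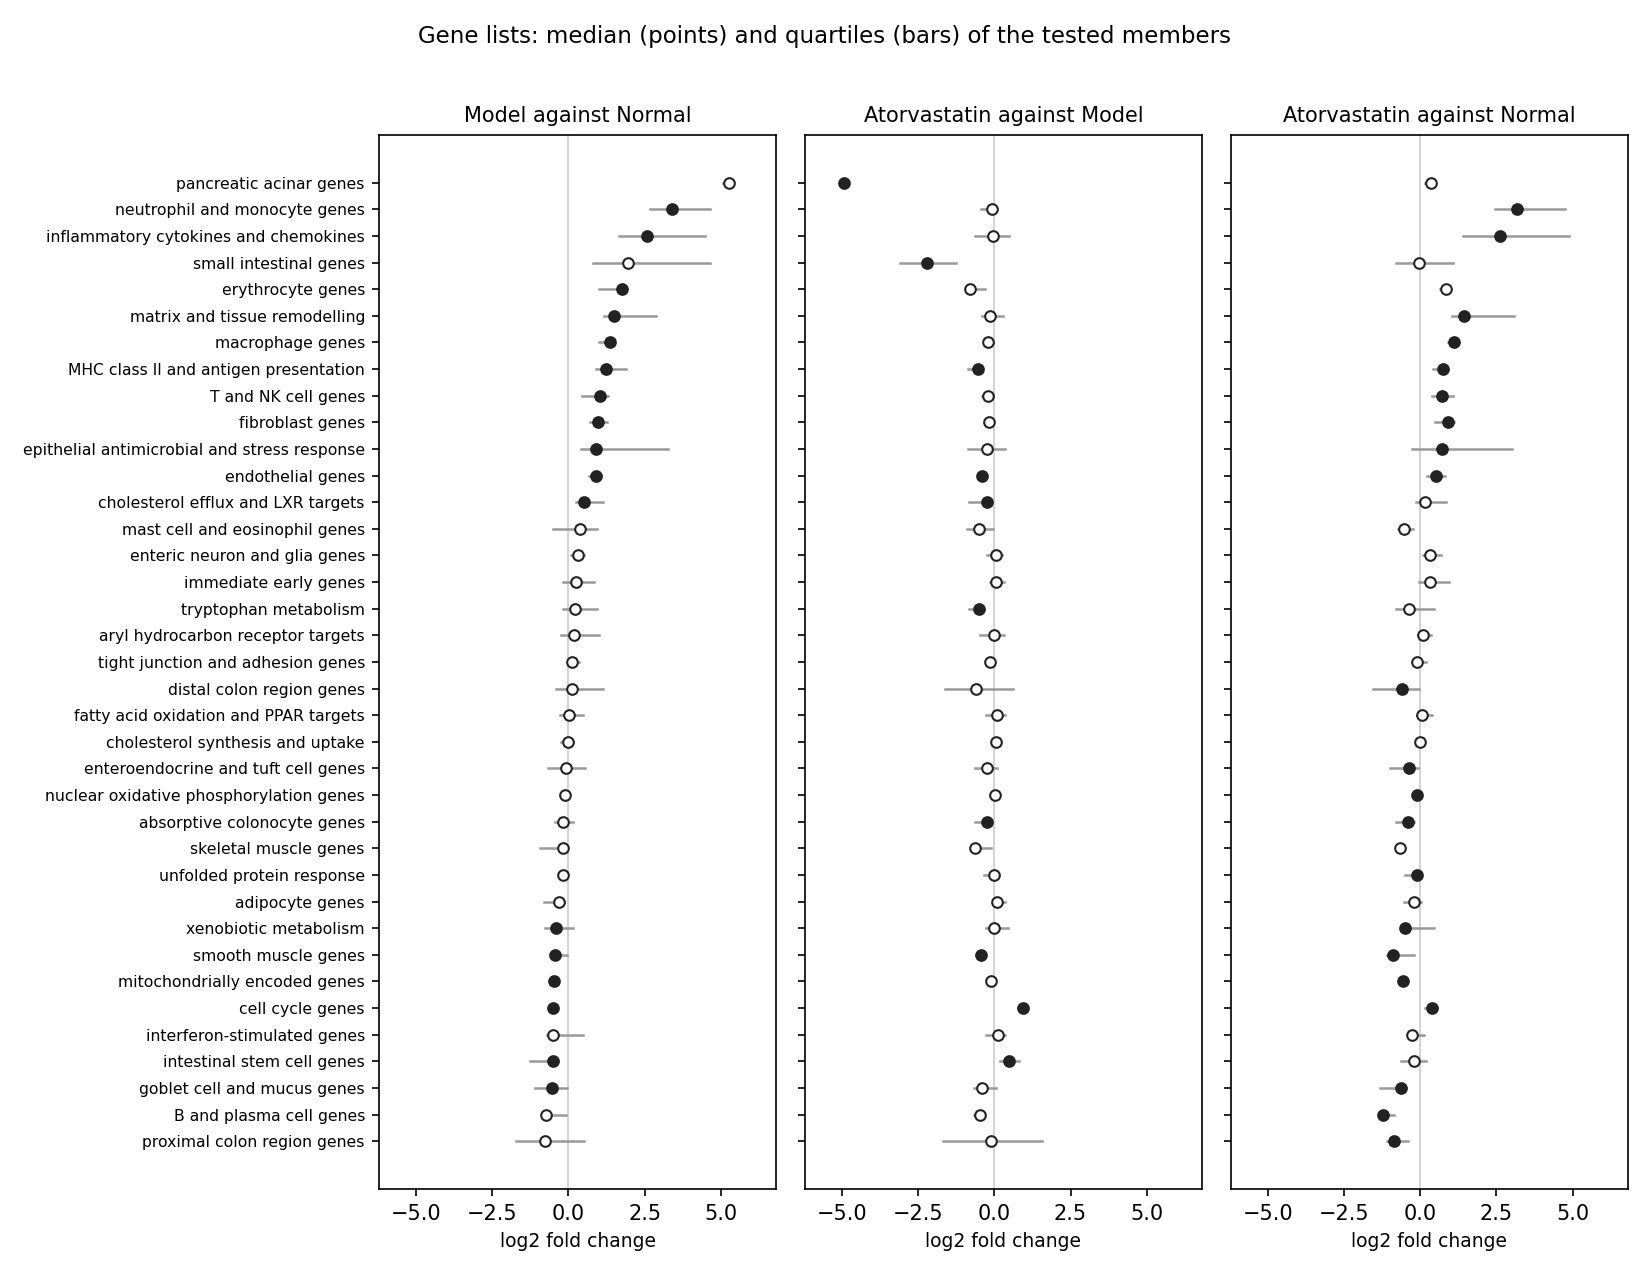
Median log2 fold change (points) and quartiles (bars) of the tested members of 37 gene lists in the 3 comparisons; filled points passed camera at an adjusted p under 0.05 with the preset correlation. Neutrophil and monocyte genes lay at 3.38 in Model against Normal and 3.18 in Atorvastatin against Normal, and cell cycle genes at 0.93 in Atorvastatin against Model; 0 of the lists held with an estimated correlation.

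**Figure D4:**
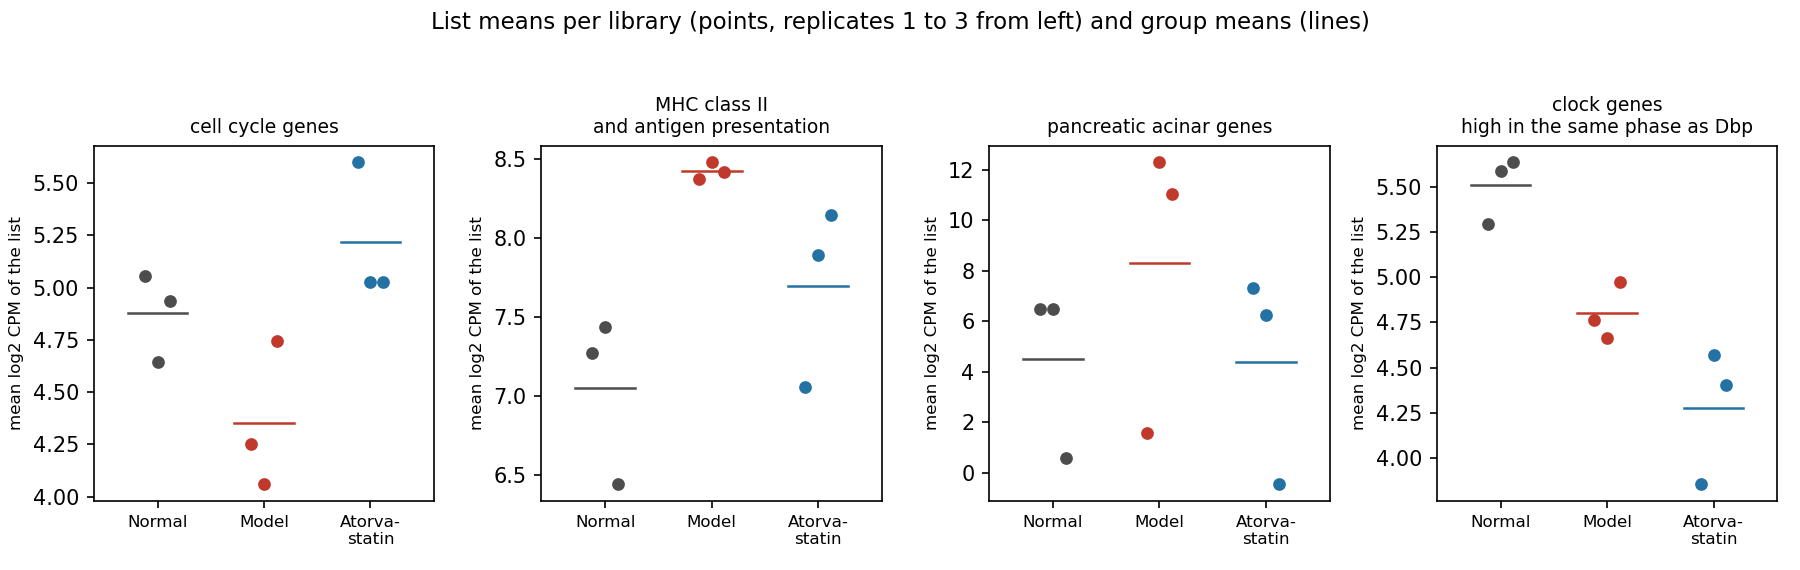
Mean log2 CPM of 4 gene lists in each library (points, replicates 1 to 3 from left to right) with group means (lines). Cell cycle genes averaged 5.22 ± 0.33 in Atorvastatin and 4.35 ± 0.35 in Model, and pancreatic acinar genes stood apart in Model 2 and Model 3; the clock list was chosen after its values were seen.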

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

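Among named genes, 5461 values kept their direction and their side of the threshold, 349 lost the call and 141 gained it. No gene that passed, as reported or under the alternative, changed direction, but 55 values that passed in neither changed sign, 8 of them by library size alone. Among list medians 1748 stayed, 141 lost and 79 gained the call, 128 that passed in neither changed sign and 13 reversed. For Model against Normal, 883 genes became 1966 by DESeq2, 474 with only the 2 groups compared, 439 with the acinar covariate and 476 omitting Model 2 and 3; leaving out 1 library gave 164 to 1164. For Atorvastatin against Model, 0 became 321 by DESeq2; leaving out 1 library gave 0 to 1. For Atorvastatin against Normal, 270 became 1056 by DESeq2, 141 by limma-voom, 436 by library size alone and 168 with the acinar covariate; leaving out 1 library gave 17 to 382. The opposite-direction share of 88.9% became 76.0% by library size alone and 94.7% omitting Model 2 and 3; leaving out 1 library gave 78.7 to 94.5%. Omitting Model 2 and 3 leaves Model 1 alone, assumed to vary like the other groups. Its noise enters both comparisons with opposite sign and raises the share, and no simulation was run for that setting, so its 94.7% was not taken as support. Fewer libraries lower the power of the fits that omit them; otherwise the cause was not tested.

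Of the lists past the threshold, 0 held with an estimated correlation in Model against Normal, 0 in Atorvastatin against Model and 0 in Atorvastatin against Normal; fry called 8, 0 and 6. In Atorvastatin against Model, 10 lists became 20 by library size alone and 16 with the region covariate. Library size alone moved the median of all genes by 0.24 in Atorvastatin against Model and 0.14 in Atorvastatin against Normal. List medians that reversed were, for Model against Normal, smooth muscle genes (0.065 omitting Model 2 and 3). For Atorvastatin against Model by library size alone they were cytokines and chemokines (0.20), neutrophil and monocyte genes (0.19) and T and NK cell genes (0.022). Omitting Model 2 and 3 reversed cholesterol synthesis and uptake (-0.17) and pancreatic acinar genes (5.07), the acinar covariate the acinar genes (0.18) and the region covariate xenobiotic metabolism (0.088). Leaving out 1 library gave -0.22 to 0.54 for interferon-stimulated genes, -0.10 to 0.22 for xenobiotic metabolism and -0.27 to 0.21 for immediate early genes. For Atorvastatin against Normal by library size alone they were the unfolded protein response (0.026) and nuclear oxidative phosphorylation genes (0.020). The cause was not tested.

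With the replicate number as a block, the counts were 402 in Model against Normal, 0 in Atorvastatin against Model and 104 in Atorvastatin against Normal, and the opposite share 86.6%. Same-numbered libraries correlated at -0.28 to 0.23, 2 of 9 over 0.1, and 2 of 9 libraries lay closest to their own number, so the numbers were not taken as a pairing. The block moved 3 list calls: pancreatic acinar genes in Model against Normal (adjusted p = 0.0346), and erythrocyte genes (0.00765) and nuclear oxidative phosphorylation genes (0.0744) in Atorvastatin against Normal.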

Other observations

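The lists of this part, and the tests of the pancreatic, clock and cell cycle patterns, were chosen after the results were seen, while the splits of the libraries were planned before. The camera values of these added lists are adjusted over their own 15 tests. Clock genes of the phase of Dbp were lower in Atorvastatin than in Normal, 11 of 11, with 6 passing (median log2 fold change -1.16, camera adjusted p = 8.30e-11, adjusted p = 0.295 with an estimated correlation). Those 6 were Dbp (-2.58, adjusted p = 0.00562), Nr1d1 (-1.95, adjusted p = 0.0133), Ciart (-1.60, adjusted p = 0.0233), Nr1d2 (-1.33, adjusted p = 0.0110), Tef (-1.17, adjusted p = 0.0133) and Per2 (-1.16, adjusted p = 0.0290). In Model against Normal 4 of the 11 fell, Dbp, Tef, Nr1d2 and Ciart (median -0.67, camera adjusted p = 1.10e-04, adjusted p = 0.376 with an estimated correlation). In Atorvastatin against Model 10 of the 11 were lower, with 0 passing in edgeR's test (median -0.50, camera adjusted p = 1.10e-04, adjusted p = 0.376 with an estimated correlation). The difference of list means there went from -0.52 to -0.31 without Atorvastatin 1. The opposite-phase list was higher in Model against Normal (median 0.55, camera adjusted p = 0.0333, adjusted p = 0.376 with an estimated correlation), and lost the call without Model 3 (adjusted p = 0.274). Of 6 opposite-phase genes Arntl and Nfil3 rose in Model (1.28, adjusted p = 0.0122; 2.66, adjusted p = 0.00470) and in Atorvastatin (1.06, adjusted p = 0.0409; 2.68, adjusted p = 0.0115).

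Of 19 hypoxia response genes 4 rose in Model against Normal, and the list passed as higher (median 0.23, camera adjusted p = 0.0318, adjusted p = 0.473 with an estimated correlation). Model 2 carried much of the rise of the list mean: without it the difference of list means went from 0.30 to 0.13. The median went from 0.23 to 0.18, and the list did not pass (camera adjusted p = 0.368). It also did not pass without Normal 3 (camera adjusted p = 0.0551). The 4 genes were Egln3 (1.41, adjusted p = 0.00431), Bnip3 (1.06, adjusted p = 0.0274), Adm (1.40, adjusted p = 0.0327) and Hk2 (1.03, adjusted p = 0.0353). In Atorvastatin against Model the list was lower with 0 passing in edgeR's test (median -0.20, camera adjusted p = 0.00828, adjusted p = 0.473 with an estimated correlation). The fall of the list mean rested on Model 2: without it the difference of list means went from -0.20 to -0.02. The median went only from -0.20 to -0.16, but the list did not pass (camera adjusted p = 0.368). It also did not pass without Atorvastatin 2 (camera adjusted p = 0.0598). Bnip3 stood at -1.04 and Egln3 at -0.90 (adjusted p = 0.322 for both).

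The acinar RNA of Model 2 and Model 3 could come from pancreas carried over with the colon or from acinar genes switched on by DSS. The islet hormone gene Ins2, which acinar cells lack, had 1068 and 91 estimated counts there, the lower of them 91 against a threshold of 12, and at most 4 in the other 7 libraries, as carry-over would give. The other tested islet genes did not stand out in Model 3: Iapp had 1.56 CPM in Model 2 and 0.175 CPM in Model 3, against 0.283 CPM in Model 1. The mean log2 CPM of Iapp and Pcsk1n was 1.38, -0.79 and 0.35 in Model 2, Model 3 and Model 1. Ins2 and Ins1 were also far lower in Model 3 than in Model 2, with Ins1 at 17 against 203 estimated counts. So low an Iapp value therefore does not count against islet RNA in Model 3. Islet RNA in Model 3 thus rests on Ins2 and on 17 estimated counts of Ins1. For induction by DSS, the lowest Model library, Model 1, lay -2.96 log2 from the Normal mean of the list. With 1 such library this test cannot tell. The mean log2 CPM of the acinar list was 6.50, 6.49 and 0.57 in Normal 1 to 3, against 1.56 in Model 1. DSS was therefore not needed for acinar RNA to appear in a library, which argues against DSS as its only source. Whether DSS added to the higher level in Model 2 and Model 3 remains open.

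The lower clock genes in Atorvastatin against Normal could come from collection at another time of day or from a lower share of epithelial cells. The opposite-phase genes had a median of -0.053, between the values that the 2 outcomes predicted, so the time of day remains open. The lower quartile of pan-epithelial genes was -0.23, against the clock median of -1.16, which rules out a lower epithelial share as the whole cause.

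The higher cell cycle genes in Atorvastatin against Model could come from a larger epithelial share, another colon region or pancreatic RNA in Model. The upper quartile of pan-epithelial genes was 0.056, against a lower quartile of 0.77 for the cell cycle genes. With the region covariate the list median was 0.89 (camera adjusted p = 3.06e-14), and with the acinar covariate 0.99 (camera adjusted p = 1.15e-13). Neither the epithelial share nor, by its covariate, pancreatic RNA accounts for the whole difference. The region score cannot exclude another colon region, since its proximal genes moved in opposite directions in this comparison. Those genes include Sycn, whose counts may come from the acinar RNA of Model 2 and 3. An effect of atorvastatin remains open, since the list call is lost with an estimated correlation (adjusted p = 0.444).

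The 6 libraries of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. Among the 10 splits, 1 gave at least as many genes as the real split in Model against Normal, the real split itself (883; highest other 1). The same count was 1 in Atorvastatin against Normal, again the real split alone (270; highest other 1), and 10 in Atorvastatin against Model (0; highest other 1). For lists it was 1 in Model against Normal (17; highest other 16) and 1 in Atorvastatin against Normal (21; highest other 18), the real split alone in both, and 9 in Atorvastatin against Model (10; highest other 19). Of 20 assignments of the Model and Atorvastatin libraries, 3 gave an opposite share of at least the real 88.9%, the real one included (highest other 94.7%), again too few for a share under 0.05. Of all 9 libraries, Atorvastatin 2 was the highest or the lowest at 7.24% of genes, the others at 17.1 to 30.6%.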
